A study of Mus musculus with 21 samples.

How the data were processed

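Gene expression was measured on 21 Illumina mouse BeadChip arrays, 1 colour each, in 7 groups of 3 arrays. The groups are undifferentiated embryonic stem (ES) cells, undifferentiated induced pluripotent stem (iPS) cells, embryoid bodies from each line at day 16, cardiomyocytes from each line at day 16, and adult mouse tail tip fibroblasts. Per the labels, RNA was extracted with TRIzol and amplified to biotin-labelled cRNA with an Ambion MessageAmp kit. Scanner software, its version and its background handling are not given in the sources used here. The labels give shared passage numbers within a line: 7, 9 and 10 for ES cells and 5, 7 and 8 for iPS cells.

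The deposited scanner table holds a mean bead signal in intensity units for each of 45281 probes and array, never negative, with no normalization between arrays. Its second deposited column per array is a detection p-value, which moves in equal steps that fit 936 negative control probes. The deposited series matrix holds intensity values that the authors quantile normalized on the linear scale, as its 21 distributions show, whose sorted values agree to a largest relative difference of 0.000868. Each of its 45281 lines has the within-array ranks of exactly 1 line of the scanner table, but only 3 of them carry the same probe identifier. Under the same identifier, Spearman's rho per array between both tables lay between 0.00400 and 0.0198, across probes. After matching by rank, the matrix equalled quantile normalized scanner signals to a largest relative difference of 4.76e-10. Genes with a pair of probes were used to tell which identifiers name the values. The median correlation over 3118 probe pairs of 1 gene was 0.858 with the scanner table's identifiers, and 87.1% of pairs exceeded 0.5. With the matrix's identifiers it was 0.270 over 2542 pairs, and 37.4% exceeded 0.5. The scanner table was therefore used, and the matrix served only as an alternative after matching by rank.

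Signals were background corrected and normalized with neqc of limma 3.58.1 in R 4.3.3, which takes the background from the detection p-values, adds an offset of 16, quantile normalizes and takes log2. The tables were read with data.table, version 1.17.8, and plots were drawn with matplotlib 3.10.9. Where replicate number served as a block, it entered the limma model as a fixed effect. Of the probes, 34903 had an entry in the gene table provided, 34885 of these with 1 symbol, and 10378 had none. The 18 probes with several symbols were left out. Each of 19057 symbols was represented by its brightest probe over all arrays. The 10900 genes with a detection p under 0.01 on all 3 arrays of at least 1 group were tested.

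One limma model with a mean per group was fitted to all groups, with trended empirical Bayes variances (12 residual and 6.32 prior degrees of freedom). A gene was called when its Benjamini-Hochberg adjusted p over the tested genes was under 0.05 and its change was at least 2-fold. The series text calls the fibroblast arrays technical replicates of single RNAs, while their labels give passages 2, 3 and 4. Their mean entered the model as 1 sample, whose variance was taken from the other groups. The 10 comparisons were iPS against ES cells, iPS cells against fibroblasts, the 3 steps of differentiation within each line, and the lines against each other in embryoid bodies and in cardiomyocytes. In addition, 2 interactions tested whether the step into embryoid bodies, and the step from embryoid bodies to cardiomyocytes, differed between the lines. With 3 arrays against 3, an exact permutation test on a single gene cannot go below a p of 0.10, so no such test was run.

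A fold change beside a group in which no array detected the probe is given as a bound. It is the bright group's mean minus the mean, over the dim group's arrays, of the larger of the gene's value and the lowest value among detected probes of that array. For both groups undetected no fold is given. Errors beside log2 differences are standard errors from the model.

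Before the data were examined, 24 gene lists were fixed, together with the comparisons, tests and alternatives. They are pluripotency, reprogramming factors, cardiac sarcomere, cardiac transcription factors and peptides, cardiac calcium handling and ion channels, fatty acid oxidation and oxidative phosphorylation, glycolysis, cell cycle, fibroblast and extracellular matrix, smooth muscle, endothelium, blood, neural, visceral endoderm and liver, skeletal muscle, epithelium, primitive streak and early mesoderm, p53 response and apoptosis, hypoxia, stress and heat shock, imprinted genes, Y chromosome and X inactivation, glutathione and xenobiotic, and interferon and antigen presentation. A list name without a probe was looked up as a synonym, unless it is itself the official symbol of a gene. The last condition was set after results had been seen, since Gpi1, Eno1 and H19 had been matched to other genes. Each list was tested with limma's camera (two-sided, preset inter-gene correlation 0.01), adjusted over the 24 lists of a comparison. An estimated correlation and fry were run beside it. Over all comparisons 110 list results were called, and 7 of them hold with an estimated correlation. Median, mean and test differed in sign in 27 of 288 list results, of which 0 were called.

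Genes named in the text follow a rule fixed with the lists. It takes the 10 largest called changes per direction whose groups do not overlap for iPS against ES cells, iPS cells against fibroblasts, and the lines in embryoid bodies and cardiomyocytes. For each step measured in both lines it takes the 8 largest per direction called in both, ranked by the smaller change. It adds the 5 largest per direction for each interaction, up to 4 called members of each list per comparison, the 8 largest per direction called between the lines at all 3 stages, and always Pou5f1, Nanog, Sox2, Klf4, Myc, Myh6, Nppa and Actc1. Myc was not among the tested genes, and clone names and numbered gene models were skipped. Levels of Dppa5a, Xist and Eif2s3y are also given in places where this rule did not name them.

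The alternatives were no background correction, an offset of 50, scaling to the 75th percentile of detected probes, no filter, probes detected on all 21 arrays only, the mean of all probes of a symbol, matrix values matched by rank, array weights, only the groups compared, replicate number as a block, 3 separate fibroblast samples and leaving out each array. A further alternative, without iPS replicate 1 and ES replicate 2, was added after seeing the data. Slide as a block was not run, since no slide is given. On simulated data with 200 of 10900 genes changed, 92.5% of the 2.5-fold changes in ES-derived embryoid bodies against ES cells were recovered, and 83.6% in iPS cells against fibroblasts. In both, 100% of the 8-fold changes were recovered. The simulated fibroblast arrays had independent noise, which their averaging lowers. For technical replicates of 1 sample the 83.6% may thus be too high. A shift of 0.5 added to the glycolysis list gave an adjusted p of 3.07e-27 and 1 called list of 24. The simulated noise was independent between genes, so this cannot show how often lists of correlated genes are called falsely.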

Results

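Transcript levels were measured on 21 arrays in 7 groups of 3. The 2 pluripotent lines both carry αPIG, a transgene that drives puromycin resistance and green fluorescent protein from the Myh6 promoter, so only cells with an active Myh6 promoter survive puromycin. The ES line is αPIG D3 and the iPS line αPIG TiB7.4. Undifferentiated cells (ES, iPS) grew on inactivated mouse embryonic fibroblasts as feeder cells. Embryoid bodies (ES-EB, iPS-EB) are the untreated aggregates of the same batches at day 16. Cardiomyocytes (ES-CM, iPS-CM) were selected with puromycin at 8 µg/ml from day 9 and taken at day 16. Adult tail tip fibroblasts serve, per the series text, as the control for iPS cells, and their 3 arrays were averaged into 1 sample.

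The median signal per array ranged from 23.6 to 33.2, and 13231 to 17866 of 45281 probes were detected. Per group, between 7532 (ES) and 8961 (iPS-EB) of the 10900 tested genes were detected on all 3 arrays. Pearson's r between arrays of a group was 0.976 to 0.997 across genes, which are not independent replicates. ES and iPS group means correlated at 0.971, ES-CM and iPS-CM at 0.971, and ES-EB and iPS-EB at 0.958, while ES and ES-CM correlated at 0.720. An array that stood apart was ES replicate 2, with the lowest median signal. Another was iPS replicate 1, whose fibroblast and extracellular matrix list averaged 7.66 on the log2 scale against 6.62 and 6.63 on the other iPS arrays. A further one was ES-EB replicate 1, whose pluripotency list averaged 8.46 against 9.14 and 9.06 and whose blood list averaged 6.05 against 5.21 and 5.26. Fibroblast replicate 3 correlated at 0.976 and 0.978 with replicates 1 and 2, which correlated at 0.996 with each other. The Y-linked Eif2s3y measured 6.97 on iPS-CM replicate 1 and 9.16 and 9.24 on the other iPS-CM arrays. Replicates of a line differ in passage, and p-values measure the spread between these cultures only. All values below are log2 differences ± standard error from 3 arrays per group, unless given as a fold or a level. A bound is given only where no array of a group detected the gene, so a difference from a group with 1 or 2 detected arrays rests in part on background. List counts adjusted over the list alone equal those over all genes tested, unless both are given.

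**Figure D1:**
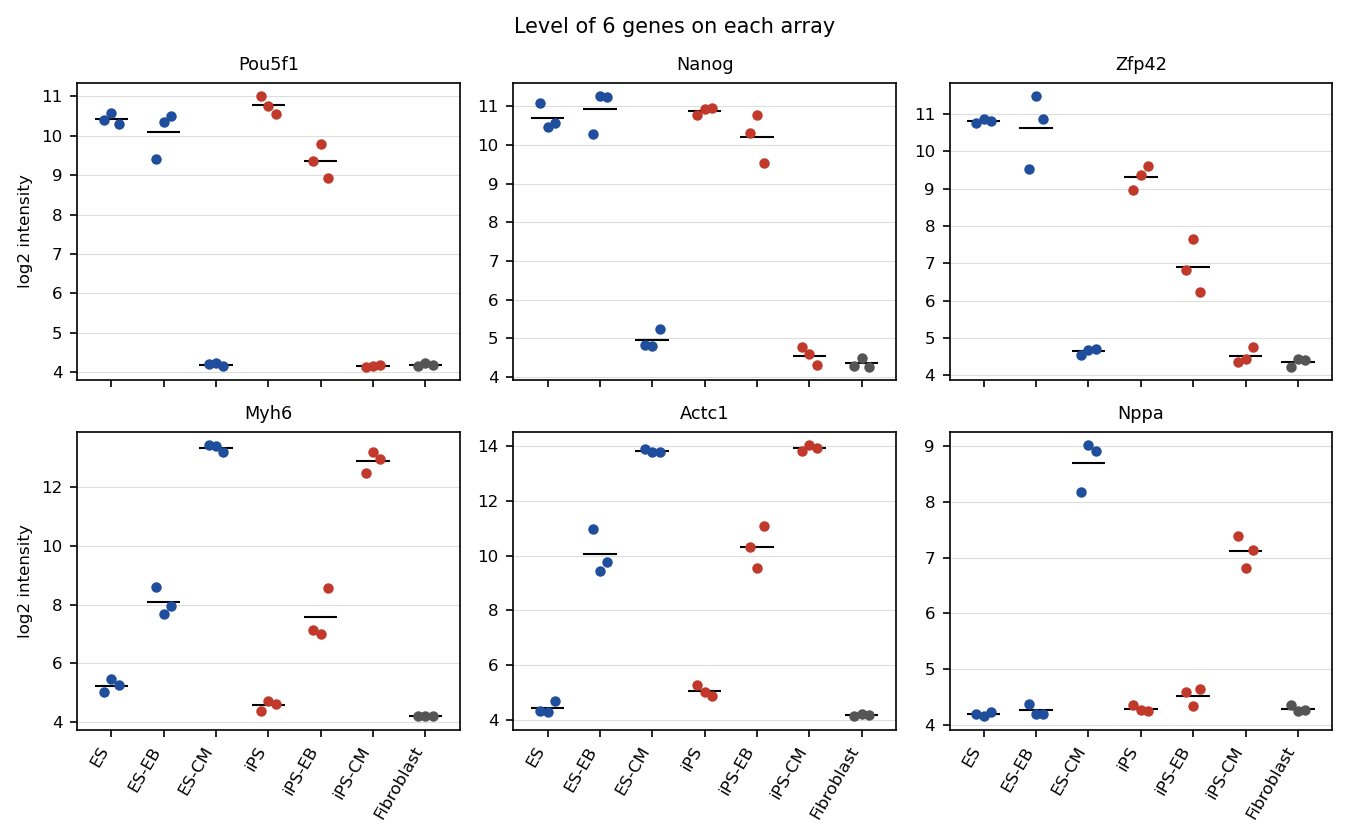
Log2 intensity (vertical axis) of 6 genes on each of 3 arrays per group (horizontal axis; points are arrays, bars are means). Pou5f1 and Nanog were near 10 or above in undifferentiated cells and fell in cardiomyocytes, while Myh6, Actc1 and Nppa were highest there.

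Undifferentiated iPS cells were compared with ES cells to see how far the reprogrammed line resembles the ES line. Pou5f1, Nanog and Dppa5a were not called. Pou5f1, the master transcription factor of pluripotency, measured 10.77 ± 0.22 (SD, n = 3) in iPS cells and 10.43 ± 0.15 in ES cells. The homeobox factor Nanog measured 10.89 ± 0.10 and 10.71 ± 0.32, and Dppa5a 13.92 ± 0.18 and 13.83 ± 0.15. The pluripotency list averaged 9.56 in iPS and 9.55 in ES cells. Of its 34 measured members 3 were higher, 2 lower and 29 not called, with an adjusted p of 0.891 for the list, and 11 had an unadjusted p under 0.05. Zfp42 was lower in iPS cells (-1.50 ± 0.36), a call that ended without iPS replicate 1 and ES replicate 2 (0.0568), left out after seeing the data. Dnmt3b was higher (1.05 ± 0.35), a call that ended without the filter on dim probes (0.0681), without ES replicate 1 (0.0835), 2 (0.0689) or 3 (0.0835), and without iPS replicate 1 (0.0888), 2 (0.0744) or 3 (0.0848). In these settings its difference stayed between 1.03 and 1.08. None of the 3 measured reprogramming factors, Pou5f1, Sox2 and Klf4, was called by limma, and 0 of them reached an unadjusted p under 0.05. That list had an adjusted p of 0.929, with a negative median and mean and a positive test direction.

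Among the largest higher levels in iPS cells were those of Olig1, a transcription factor of the oligodendrocyte lineage (4.79 ± 0.20), the mitotic kinase Plk1 (4.20 ± 0.22), the signalosome subunit Cops8 (4.17 ± 0.17) and the growth factor Fgf5 (3.98 ± 0.36). Of the 3 ES arrays, 1 detected Olig1, Plk1 and Cops8, and 2 detected Fgf5. Plk1 and Cops8 had no other detected probe to compare, so their differences rest on a single probe each. Genes of the primitive streak, the site of gastrulation, were higher together: 6 of 10 measured members were called higher and 0 lower. Fgf8 was at least 12.6-fold, Lhx1 at least 6.07-fold and Evx1 at least 3.51-fold higher, all 3 not well above background in ES cells. Gsc, an organizer homeobox gene, was higher by 3.17 ± 0.33, and Nodal, a ligand named from the pluripotency list, by 1.54 ± 0.27. The primitive streak list's adjusted p was 6.51e-06, and its adjusted p = 0.466 with an estimated correlation. Also higher were the protein import receptor Tomm22 (3.22 ± 0.15 at the probe used), the chemokine Ccl27a (at least 6.36-fold), the lysosomal protease Ctsc (at least 4.85-fold), the splicing regulator Esrp1 (1.53 ± 0.36) and the tight junction gene Cldn6 (1.15 ± 0.31). Lower in iPS cells were the X-linked Xlr4a (-3.13 ± 0.20), the elastase Cela2a (-2.94 ± 0.16), the lipase Liph (-2.90 ± 0.28), Khdc3 (-2.63 ± 0.18), the kinase Aurkc (-2.62 ± 0.19), the chaperone Clgn (-2.61 ± 0.16) and Tex14 (-2.38 ± 0.31).

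Genes of fibroblasts and extracellular matrix were higher in iPS than in ES cells, 12 of 33 by the test over all genes and 13 adjusted over the list alone. The matrix protease Mmp3 was higher by 2.42 ± 0.22, and the proteoglycan Lum was at least 2.57-fold higher. The adjusted p was 5.12e-06, and the adjusted p = 0.805 with an estimated correlation. This group moved with 1 array: the list averaged 7.66 in iPS replicate 1, 6.62 and 6.63 in replicates 2 and 3, and between 6.16 and 6.17 in ES cells. Without iPS replicate 1, 5 members were higher, with an adjusted p of 0.0013. Endothelial genes were on balance lower, 3 of 18 lower and 1 higher, with Pecam1 at -2.05 ± 0.31 and the receptor Flt1 at 2.07 ± 0.25. The endothelium list had an adjusted p of 0.0144, and an adjusted p = 0.335 with an estimated correlation. Without iPS replicate 1 and ES replicate 2, left out after seeing the data, that call ended (0.0676). Smooth muscle genes were higher in 2 of 9 cases, and 4 adjusted over the list alone (0.0288, adjusted p = 0.805 with an estimated correlation). That call ended without ES replicate 1 (0.123) or iPS replicate 1 (0.177), under 75th percentile scaling (0.0734), with array weights (0.0714), without the filter on dim probes (0.133), with genes detected on all 21 arrays (0.41) and with the combination chosen later (0.0731). The skeletal muscle gene Actn3 (-1.48 ± 0.17) was lower and the axon guidance gene Dpysl3 (1.25 ± 0.17) higher.

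In total 299 genes were higher and 249 lower in iPS than in ES cells (limma, Benjamini-Hochberg, over 10900 genes). With an offset of 50 the counts were 119 and 89. Not called were glycolysis (adjusted p = 0.177), imprinted genes (0.367), and cell cycle (0.646), in which Plk1 alone of 32 members was higher.

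Compared with the fibroblasts, iPS cells showed the pluripotency genes at very different levels. Dppa5a was higher by 9.43 ± 0.30 and the DNA methyltransferase Dnmt3b by 7.35 ± 0.50. Dppa4 was at least 120-fold, Esrrb at least 92.7-fold, Sall4 at least 79.9-fold, Nanog at least 77.6-fold, Pou5f1 at least 71.4-fold and Sox2 at least 9.76-fold higher, none of them well above background in fibroblasts. Klf4, in contrast, measured 8.74 ± 0.15 (SD, n = 3) in iPS cells and 9.11 in fibroblasts, whose arrays count as 1 sample. Its difference was not called (-0.36 ± 0.77). Of the pluripotency list 31 of 34 members were higher and 0 lower (adjusted p = 1.44e-15, and adjusted p = 0.273 with an estimated correlation). Epithelial junction genes were higher as well, 9 of 13 (7.86e-05, adjusted p = 0.436 with an estimated correlation), among them E-cadherin, Cdh1 (4.44 ± 0.25), and Cldn6 (at least 38.8-fold). Cell cycle genes were higher in 28 of 32 cases and lower in 1 (1.34e-11, adjusted p = 0.325 with an estimated correlation), such as Mcm5 (3.54 ± 0.16), Mcm2 (3.53 ± 0.19) and Aurka (3.52 ± 0.29). Glycolysis genes were higher in 7 of 18 cases (0.0399, adjusted p = 0.48 with an estimated correlation), a call that ended without iPS replicate 1 (0.055) or fibroblast replicate 2 (0.0526) and with the mean of all probes (0.068). The members of this list were corrected after results had been seen, and before that it was not called. Primitive streak genes were higher in 5 of 10 cases (0.024, adjusted p = 0.487 with an estimated correlation). The glucose transporter Slc2a3 was higher by 6.05 ± 0.30 and the imprinted growth inhibitor Phlda2 at least 34.7-fold.

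Fibroblasts were brighter in matrix genes: 31 of 33 list members were lower in iPS cells (1.24e-11, adjusted p = 0.325 with an estimated correlation). The crosslinking enzyme Lox differed by -6.08 ± 0.53, Col3a1 by -5.59 ± 0.37, and Col1a2 was at least 45.5-fold lower. Genes of macrophages and other blood cells were among those with the largest differences in this direction. The lysozyme Lyz2 was at -8.82 ± 0.38, the chemokine Ccl4 at -8.13 ± 0.31, and the complement gene C1qb was at least 119-fold lower in iPS cells. Fcer1g was at least 85.1-fold, Ms4a6d at least 75.3-fold and Cd52 at least 60.6-fold lower. The blood list averaged 4.96 ± 0.07 (SD, n = 3) in iPS cells and 8.61 in fibroblasts, whose arrays count as 1 sample. Of its 12 members 8 were lower in iPS cells (1.23e-05, adjusted p = 0.273 with an estimated correlation). Interferon and antigen presentation genes were lower in 13 of 18 cases (0.00164, adjusted p = 0.436 with an estimated correlation), such as B2m (-3.71 ± 0.34) and H2-D1 (-3.29 ± 0.29). Smooth muscle genes were lower in 7 of 9 cases (0.016, adjusted p = 0.48 with an estimated correlation), such as Mylk (-4.21 ± 0.37). Xist, the RNA of the inactive X chromosome, measured 9.58 in fibroblasts and 5.08 ± 0.80 (SD, n = 3) in iPS cells. The Y-linked Eif2s3y was detected on all 3 fibroblast arrays with a mean of 6.50, and measured 8.26 ± 0.13 (SD) in iPS cells. That list was not called (0.902), and its median was positive while its mean and test were negative.

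Against fibroblasts 2166 genes were higher and 2277 lower in iPS cells. The fibroblasts are 1 sample, whose spread was taken from the other groups. Whether that culture held other cells or came from several animals is not given, so differences in blood, interferon and X- or Y-linked genes hold for this sample and not for fibroblasts as a cell type. The calls of the lists pluripotency (0.114), glycolysis (0.114), smooth muscle (0.207) and interferon and antigen presentation (0.207) ended when only genes detected on all 21 arrays were tested. Neural genes were not called (0.454).

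The step from undifferentiated cells to embryoid bodies was followed in each line. In both lines the genes of the cardiac contractile apparatus appeared. Cardiac troponin C, Tnnc1, was at least 36.1-fold higher in ES-EB than in ES and at least 49.3-fold in iPS-EB than in iPS. Myosin light chains followed, Myl3 at least 32.7-fold and 43.2-fold, Myl2 at least 31.8-fold and 41.7-fold, and cardiac actin, Actc1, at least 36.6-fold in the ES line and by 5.25 ± 0.32 in the iPS line. Myh6, the alpha myosin heavy chain whose promoter drives the selection, rose by 2.84 ± 0.31 and 3.00 ± 0.31 in these unselected aggregates. Of 24 sarcomere genes 12 rose in the ES line (3.19e-08, adjusted p = 0.376 with an estimated correlation) and 13 in the iPS line (4.46e-09, adjusted p = 0.28 with an estimated correlation). Cardiac transcription factors rose in 6 of 19 cases in the ES line (0.00714, adjusted p = 0.376 with an estimated correlation) and in 8 in the iPS line (0.000144, adjusted p = 0.28 with an estimated correlation). Isl1, a factor of cardiac progenitors, was at least 4.93-fold and 8.61-fold higher, and Gata6 was at least 10.7-fold higher in the ES line and rose by 3.52 ± 0.29 in the iPS line. Calcium handling genes rose in 8 of 25 cases in the iPS line (0.00475, adjusted p = 0.296 with an estimated correlation), while in the ES line 4 rose and 1 fell (0.0842, and 0.045 without ES-EB replicate 2). Popdc2 rose by 2.30 ± 0.31 in the ES line and was at least 5.39-fold higher in the iPS line.

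Other tissues appeared too. The visceral endoderm and liver list rose in 8 of 21 members in the ES line (0.000489, adjusted p = 0.376 with an estimated correlation). In the iPS line 13 rose, and 14 adjusted over the list alone (7.61e-05, adjusted p = 0.28 with an estimated correlation). The thyroxine carrier Ttr was at least 16.5-fold and 18.5-fold higher, and Spink1 rose by 2.72 ± 0.25 and 3.11 ± 0.25. Endothelial genes rose in 8 of 18 cases and fell in 1 in the ES line (0.0259, adjusted p = 0.295 with an estimated correlation), a call that ended under 75th percentile scaling (0.0518). The iPS line had 4 rising (0.0469, adjusted p = 0.28 with an estimated correlation), and the call ended without iPS replicate 1 (0.0877) or iPS-EB replicate 3 (0.104) and with the replicate block (0.056), among other settings. The endothelial gene Emcn was at least 5.67-fold and 3.55-fold higher, and the endothelin receptor Ednrb rose by 4.02 ± 0.23 and 4.35 ± 0.23. Neural genes rose in 5 of 14 cases in the iPS line (0.00562, adjusted p = 0.333 with an estimated correlation). The ES line had 4 rising (0.0414, adjusted p = 0.605 with an estimated correlation), a call that ended without ES replicate 3 (0.0646) or ES-EB replicate 1 (0.122), among other settings. Primitive streak genes rose in 4 of 10 cases in the iPS line (0.0174, adjusted p = 0.38 with an estimated correlation), a call that ended without iPS-EB replicate 3 (0.0802) and with only the groups compared (0.0501). Imprinted genes rose in 8 of 20 cases and fell in 1 in the ES line (0.00133, adjusted p = 0.376 with an estimated correlation), and rose in 7 and fell in 1 in the iPS line (0.00306, adjusted p = 0.296 with an estimated correlation). Of these the growth factor Igf2 rose by 3.46 ± 0.27 and 3.35 ± 0.27, and Dlk1 by 3.61 ± 0.20 and 4.81 ± 0.20. The macrophage gene Lyz2 was at least 6.35-fold higher in ES-EB than in ES, and among the ES-EB arrays the blood list was brightest on replicate 1.

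Pluripotency genes fell only in part at this step. In the ES line 10 of 34 fell (0.000284, adjusted p = 0.532 with an estimated correlation), with Lefty1 at -2.18 ± 0.18 and Dppa3 at -1.58 ± 0.28. In the iPS line 19 fell (4.06e-09, adjusted p = 0.28 with an estimated correlation), with Fbxo15 at -2.72 ± 0.29 and Klf5 at -2.27 ± 0.39. Nanog still measured 10.94 ± 0.56 (SD, n = 3) in ES-EB and 10.21 ± 0.62 in iPS-EB, and Pou5f1 10.09 ± 0.60 and 9.36 ± 0.44. Glycolytic genes fell in 10 of 18 cases in the ES line (3.86e-06, adjusted p = 0.159 with an estimated correlation), such as Slc2a1 (-1.75 ± 0.17) and Pgam1 (-1.67 ± 0.14). In the iPS line 5 fell and the muscle forms Eno3 (1.47 ± 0.25) and Pgam2 (1.77 ± 0.24) rose (0.0105, adjusted p = 0.296 with an estimated correlation). Glutathione and xenobiotic genes fell in 4 of 19 cases in the ES line (0.00714, adjusted p = 0.159 with an estimated correlation) and in 5 in the iPS line (0.000144). This last call holds with an estimated correlation (adjusted p = 0.0296), and Gpx2 fell by 2.10 and 1.39 (SE 0.27 each). The immediate early gene Fos fell by 3.75 and 3.52 (SE 0.70 each), the chemokine Cxcl1 by 2.85 ± 0.35 in the ES line and at least 24.3-fold in the iPS line, and Mmp3 at least 7.64-fold and 40.7-fold. Undifferentiated cells grew on feeder fibroblasts. Whether loss of feeder RNA contributed to falls of fibroblast and matrix genes from undifferentiated cells, such as that of Mmp3, was not tested. Cell cycle genes fell in 3 of 32 cases in the ES line (0.00714, adjusted p = 0.632 with an estimated correlation) and in 3 in the iPS line (0.00231, adjusted p = 0.44 with an estimated correlation). The cyclin Ccne1 fell by 1.76 and 2.19 (SE 0.19 each), and the replication factor Mcm2 by 1.74 ± 0.14 in the iPS line.

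Fibroblast and matrix genes went opposite ways. Of 33 members 9 rose and 3 fell in the ES line, and 4 fell adjusted over the list alone (0.0214, adjusted p = 0.632 with an estimated correlation). The iPS line had 4 rising and 10 falling (0.0461, adjusted p = 0.694 with an estimated correlation), a call that ended without iPS replicate 1 (0.28) or iPS-EB replicate 2 (0.316) and with the replicate block (0.056), among other settings. Stress and heat shock genes fell in 5 of 23 cases and rose in 1 in the ES line (0.0431, adjusted p = 0.376 with an estimated correlation), a call that ended without ES replicate 1 (0.149) or ES-EB replicate 1 (0.21), among other settings. The iPS line had 6 falling (0.0165, adjusted p = 0.296 with an estimated correlation). Interferon and antigen presentation genes fell in that line in 4 of 18 cases and rose in 1 (0.00287, adjusted p = 0.296 with an estimated correlation), a call that ended with genes detected on all 21 arrays (0.159). Reprogramming factors fell there in 2 of 3 cases (0.0469, adjusted p = 0.333 with an estimated correlation). That call ended without iPS replicate 1 (0.0788), iPS replicate 2 (0.0555) or iPS-EB replicate 3 (0.0904) and with the replicate block (0.056), among other settings. In all, 12 lists were called in the ES line and 16 in the iPS line.

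At this step 775 genes rose and 429 fell in the ES line, and 827 and 549 in the iPS line, with 431 and 200 shared where 58.8 and 21.6 would be expected of independent lists. Across genes, which are not independent replicates, both lines' changes correlated with r = 0.704 and rho = 0.673. Tested on genes detected on all 21 arrays only, calls ended in the ES line for sarcomere (0.133), pluripotency (0.197) and cell cycle (0.0868). In the iPS line the pluripotency call ended likewise (0.059). The ES line's call for cardiac transcription factors ended under 75th percentile scaling (0.0613).

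**Figure D2:**
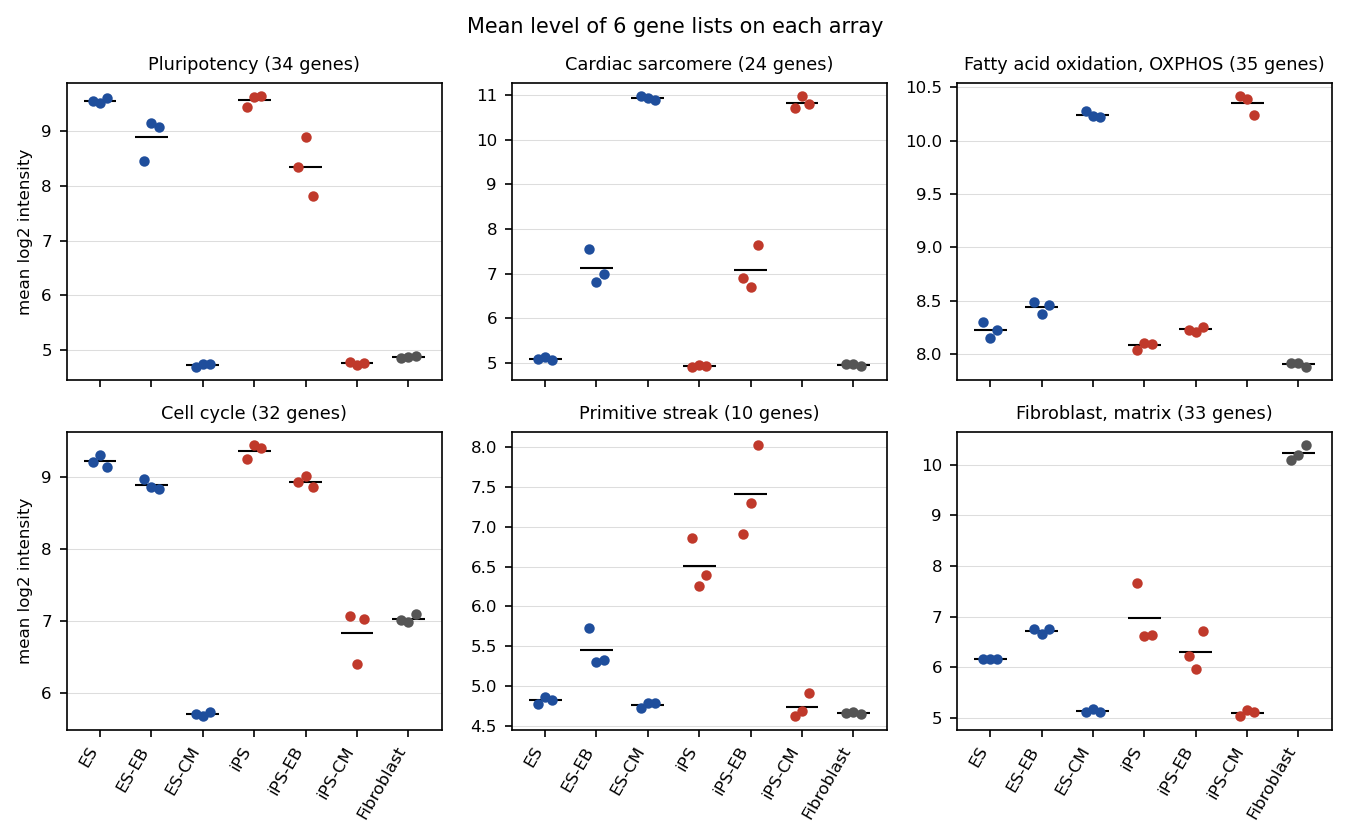
Mean log2 intensity (vertical axis) of the measured members of 6 gene lists on each of 3 arrays per group (horizontal axis; points are arrays, bars are means). The pluripotency list averaged 9.55 in ES cells and 4.74 in ES-CM, and the cell cycle list 5.70 in ES-CM and 6.83 in iPS-CM.

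Cardiomyocytes were compared with the unselected embryoid bodies of the same line to describe what the selection enriched. Sarcomere genes rose further, 22 of 24 in the ES line and 21 in the iPS line, while Tpm1 fell in both. Titin, Ttn, rose by 5.31 ± 0.30 and 5.29 ± 0.30, Tcap by 5.48 ± 0.26 and 5.65 ± 0.26, and myoglobin, Mb, by 5.13 ± 0.29 and 6.09 ± 0.29. Myh6 rose by 5.27 ± 0.31 and 5.34 ± 0.31, which is not independent of the selection through its promoter. The sarcomere list was called at 8.44e-12 in the ES line (adjusted p = 0.142 with an estimated correlation) and 1.82e-12 in the iPS line (adjusted p = 0.134 with an estimated correlation). Calcium handling and ion channel genes rose in 20 of 25 cases in the ES line (1.26e-10) and 18 in the iPS line (4.13e-10), with 1 falling in each. The call holds with an estimated correlation in the ES line (adjusted p = 0.0303) and not in the iPS line (adjusted p = 0.0542 with an estimated correlation). The ryanodine receptor Ryr2 rose by 5.28 ± 0.22 and 4.79 ± 0.22, and the calcium-binding Hrc by 5.29 ± 0.19 and 4.38 ± 0.19. Cardiac transcription factors and peptides rose in 14 of 19 cases in each line (3.58e-08 and 2.47e-07). With an estimated correlation the adjusted p = 0.0572 in the ES line and adjusted p = 0.0799 in the iPS line. Hopx rose by 4.62 ± 0.18 and 5.29 ± 0.18, Myocd by 4.66 ± 0.22 and 3.29 ± 0.22, and Ankrd1 by 5.37 ± 0.37 and 4.70 ± 0.37.

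Mitochondrial energy genes rose with them, and this group's calls hold with an estimated correlation in both lines. Of 35 genes of fatty acid oxidation and oxidative phosphorylation 24 rose in the ES line (4.21e-12, adjusted p = 0.00526 with an estimated correlation) and 31 in the iPS line (6.53e-16, adjusted p = 0.00127 with an estimated correlation), and 0 fell. The muscle subunits Cox8b (5.87 ± 0.38 and 5.12 ± 0.38) and Cox6a2 (5.08 ± 0.24 and 5.27 ± 0.24), the fatty acid carrier enzyme Cpt1b (4.22 ± 0.18 and 3.98 ± 0.18) and the coactivator Ppargc1a (3.95 ± 0.23 and 4.75 ± 0.23) were among them. In glycolysis the muscle isoforms Eno3 (4.69 ± 0.25 and 4.57 ± 0.25) and Pgam2 (4.32 ± 0.24 and 4.45 ± 0.24) rose, and the transporter Slc2a3 fell by 5.45 and 5.25 (SE 0.21 each). That list was called in the iPS line (0.0151, adjusted p = 0.315 with an estimated correlation) and missed the threshold in the ES line (0.073), where it passed without ES-EB replicate 1 (0.0359). It also passed there under 75th percentile scaling (0.0134), with the mean of all probes (0.0411) and without the filter on dim probes (0.0376).

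Pluripotency genes fell in 30 of 34 cases in the ES line (1.24e-14, adjusted p = 0.111 with an estimated correlation) and 31 in the iPS line (1.84e-13, adjusted p = 0.134 with an estimated correlation). Dppa5a fell by 8.18 and 7.62 (SE 0.21 each), and Dnmt3b by 6.02 and 7.83 (SE 0.35 each). Pou5f1 was at least 39.5-fold and 24.7-fold lower and not well above background in either cardiomyocyte group. The hormone precursor Trh, at least 113-fold and 90-fold lower, and the oocyte gene Ooep, at least 105-fold and 37.3-fold lower, went with them. Cell cycle genes fell in 30 of 32 cases in the ES line (1.69e-15, adjusted p = 0.111 with an estimated correlation) and 31 in the iPS line (3.61e-13, adjusted p = 0.134 with an estimated correlation). The thymidylate synthase Tyms fell by 5.12 and 3.00 (SE 0.22 each), and Mcm6 by 4.76 and 2.74 (SE 0.18 each). Markers of several other tissues were lower in the cardiomyocytes. Epithelial genes fell in 11 of 13 cases in the ES line (0.000104, adjusted p = 0.339 with an estimated correlation) and 9 in the iPS line (7.93e-06, adjusted p = 0.234 with an estimated correlation), such as keratin Krt8 (-3.80 ± 0.41 and -5.89 ± 0.41). Endothelial genes fell in 12 of 18 cases in the ES line (6.3e-06), a call that holds with an estimated correlation (adjusted p = 0.0105), and 8 in the iPS line (0.00238, adjusted p = 0.0791 with an estimated correlation). Egfl7 fell by 4.12 and 3.59 (SE 0.19 each). Visceral endoderm and liver genes fell in 13 and 14 of 21 cases (0.015 and 0.00518), with adjusted p = 0.431 and adjusted p = 0.315 with an estimated correlation. Primitive streak genes fell in 9 of 10 cases in the iPS line (0.000268, adjusted p = 0.234 with an estimated correlation), where Eomes was at least 11.8-fold lower. In the ES line 4 fell and that list was not called (0.223).

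The fibroblast and matrix list also fell, 17 of 33 members in the ES line (0.00128, adjusted p = 0.475 with an estimated correlation) and 14 in the iPS line (0.00763, adjusted p = 0.57 with an estimated correlation). The proteoglycan Dcn was at least 56.8-fold and 20-fold lower. Neural genes fell in 8 of 14 cases in the ES line (0.00546, adjusted p = 0.415 with an estimated correlation) and 10 in the iPS line (0.00348, adjusted p = 0.315 with an estimated correlation), such as Stmn2, at least 16-fold and 20-fold lower. Interferon and antigen presentation genes fell in 7 of 18 cases in each line (0.0176 and 0.0151), with adjusted p = 0.431 and adjusted p = 0.344 with an estimated correlation. Ifitm3 was at least 40.6-fold and 37.9-fold lower. Skeletal muscle genes went the other way. Of 8 members 6 rose and 1 fell in the ES line (0.0412, adjusted p = 0.184 with an estimated correlation), with the creatine kinase Ckm at least 3.83-fold higher and Mylpf at -2.20 ± 0.25. That call ended under 75th percentile scaling (0.0915), with the mean of all probes (0.0613), without the filter on dim probes (0.224) and with only the groups compared (0.0667). The iPS line had 3 rising (0.0423, adjusted p = 0.211 with an estimated correlation), with the receptor subunit Chrng at least 6.12-fold higher, and the call ended without iPS-CM replicate 1 (0.0648) or iPS-EB replicate 1 (0.0549). It ended as well with the mean of all probes (0.0562), without the filter on dim probes (0.141) and with only the groups compared (0.0786). Smooth muscle genes were not called (0.295 and 0.59), with a negative median and a positive mean and test in the iPS line. Reprogramming factors fell in 3 of 3 cases in each line (0.0176 and 0.0263), with adjusted p = 0.327 and adjusted p = 0.315 with an estimated correlation. These calls ended with only the groups compared in the ES line (0.059) and with an offset of 50 in the iPS line (0.0507). Imprinted genes fell in 8 of 20 cases and rose in 1 in the iPS line (0.0297, adjusted p = 0.402 with an estimated correlation). That call ended without iPS-EB replicate 3 (0.0542), under 75th percentile scaling (0.0505) and with genes detected on all 21 arrays (0.909). Not called in either line were blood (0.108 and 0.244), hypoxia (0.849 and 0.777), p53 response and apoptosis (0.71 and 0.59), and stress and heat shock (0.849 and 0.482). In the last, the heme oxygenase Hmox1 rose by 2.37 ± 0.24 in the ES line and the chaperone Hsp90aa1 fell by 2.97 and 2.44 (SE 0.21 each).

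In the ES line 1758 genes rose and 1978 fell from embryoid bodies to cardiomyocytes, and 1522 and 1817 in the iPS line. Shared were 1195 and 1400, where 246 and 330 would be expected of independent lists, and changes correlated with r = 0.885 and rho = 0.874 across genes. Testing only genes detected on all 21 arrays excludes genes that some group lacks. There the calls ended for sarcomere (0.875 and 0.946, the iPS line's median shrinking to 0.0511 with a test of negative direction), calcium handling (0.0848 and 0.0769), fibroblast (0.875 and 0.909), neural (0.875 and 0.909) and interferon (0.0848 and 0.0769). In the iPS line alone pluripotency (0.0769) and glycolysis (0.289) ended as well.

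Against undifferentiated cells the cardiomyocytes of both lines showed the full span. Tnnc1 was at least 585-fold higher in ES-CM and at least 610-fold in iPS-CM, Myl2 at least 573-fold and 549-fold, and Csrp3, a protein of the Z disc, at least 331-fold and 400-fold. Myh6 rose by 8.11 ± 0.31 and 8.33 ± 0.31. Myocd was at least 47.7-fold higher in ES-CM, and Gata6 at least 87.7-fold in ES-CM and by 5.61 ± 0.29 in iPS-CM. Sarcomere genes rose in 22 and 21 of 24 cases (3.5e-12 and 1.64e-12), with adjusted p = 0.13 and adjusted p = 0.167 with an estimated correlation. Genes of fatty acid oxidation and oxidative phosphorylation rose in 23 and 27 of 35 cases (2.01e-10 and 1.64e-12), calls that hold with an estimated correlation (adjusted p = 0.0107 and adjusted p = 0.00456). Pluripotency genes fell in 32 of 34 cases in each line (1.24e-14 and 1.88e-14), with adjusted p = 0.114 and adjusted p = 0.163 with an estimated correlation. Trh was at least 223-fold and 295-fold lower, and Lefty1 at least 57-fold and 67.8-fold lower. Cell cycle genes fell in 30 and 29 of 32 cases (1.24e-14 and 1.64e-12), with adjusted p = 0.114 and adjusted p = 0.178 with an estimated correlation. E-cadherin, Cdh1, fell by 4.67 ± 0.18 in ES-CM and was at least 18.9-fold lower in iPS-CM, in an epithelium list with 10 and 9 of 13 members lower (0.000733 and 0.000172), and adjusted p = 0.422 and adjusted p = 0.298 with an estimated correlation.

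Cardiac transcription factors rose in 15 and 16 of 19 cases (2.05e-08 and 1.7e-08), with adjusted p = 0.0694 and adjusted p = 0.0673 with an estimated correlation. Calcium handling genes rose in 20 and 18 of 25 and fell in 1 each (1.03e-08 and 1.46e-08), with adjusted p = 0.0694 and adjusted p = 0.0673 with an estimated correlation. Reprogramming factors fell in 3 of 3 (0.0292 and 0.0239), with adjusted p = 0.347 and adjusted p = 0.281 with an estimated correlation. Interferon and antigen presentation genes fell in 10 of 18 and rose in 1 in each line (0.0392 and 0.00165), with adjusted p = 0.506 and adjusted p = 0.281 with an estimated correlation. For the ES line that call ended with only the groups compared (0.0569) and without iPS replicate 1 and ES replicate 2 (0.055), left out after seeing the data. Endothelial genes fell in 10 of 18 in the ES line (0.00489, adjusted p = 0.0797 with an estimated correlation). Fibroblast and matrix genes fell in 18 of 33 and rose in 1 in the iPS line (0.000729, adjusted p = 0.47 with an estimated correlation), and primitive streak genes fell in 6 of 10 (0.0239, adjusted p = 0.449 with an estimated correlation). Stress and heat shock genes fell there in 10 of 23 and rose in 1 (0.0318, adjusted p = 0.281 with an estimated correlation), a call that ended without iPS replicate 1 (0.0502).

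In the ES line 2225 genes were higher and 2284 lower in cardiomyocytes than in undifferentiated cells, and 2180 and 2291 in the iPS line. Shared were 1728 and 1761, against 445 and 480 expected of independent lists, with r = 0.916 and rho = 0.897 across genes and 8 genes called in opposite directions. With genes detected on all 21 arrays the calls ended for sarcomere (0.496 and 0.588), calcium handling (0.0662 and 0.0567), interferon (0.248 and 0.0567) and, in the iPS line, fibroblast and matrix genes (0.732).

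Embryoid bodies of the iPS line were compared with those of the ES line. Primitive streak genes were higher in iPS-EB, 8 of 10 measured and 0 lower. Lhx1 was higher by 3.52 ± 0.36, Eomes, a regulator of mesendoderm, by 3.05 ± 0.21, Fgf8 by 2.97 ± 0.30 and Gsc by 2.89 ± 0.33. The list was called at 4.38e-07, with an adjusted p = 0.276 with an estimated correlation. Olig1 (4.60 ± 0.20), Plk1 (3.89 ± 0.22), Cops8 (at least 16-fold), Fgf5 (3.21 ± 0.36), the receptor Flt1 (2.87 ± 0.25) and the junction gene Cldn6 (2.61 ± 0.31) were higher as well. The endodermal factor Foxa1 (1.73 ± 0.20) and the retinoic acid hydroxylase Cyp26a1 (2.00 ± 0.29) were also higher. Lower in iPS-EB were the crystallin Cryba1 (-5.39 ± 0.30), the placental protease Ctsj (-5.19 ± 0.36), Xlr4a (-4.82 ± 0.20), the lysozymes Lyz1 (-4.38 ± 0.48) and Lyz2 (-3.22 ± 0.27), Aard (-4.32 ± 0.32) and the homeobox gene Rhox9 (-3.99 ± 0.40). Of 34 pluripotency genes 9 were lower and 5 higher, 25 had an unadjusted p under 0.05, and the list was called lower (0.0425, adjusted p = 0.629 with an estimated correlation). That call ended without ES-EB replicate 2 (0.0914), ES-EB replicate 3 (0.0739) or iPS-EB replicate 3 (0.267), among other settings. Zfp42 (-3.72 ± 0.36) and Fbxo15 (-3.24 ± 0.29) were lower, while Dnmt3b (1.88 ± 0.35) and Lin28a (2.11 ± 0.31) were higher, the call for Lin28a ending with the mean of all probes. The stress gene Gadd45a (-2.53 ± 0.20) and the noncoding imprinted RNA Rian (at least 7.19-fold lower) were lower too. Endothelial genes were on balance lower, 3 of 18 lower and 2 higher, with Esam at -2.18 ± 0.14 and Pecam1 at -1.76 ± 0.31 (0.0102, adjusted p = 0.232 with an estimated correlation), a call that ended under 75th percentile scaling (0.0542). Fibroblast and matrix genes were lower in 7 of 33 cases (0.0425, adjusted p = 0.629 with an estimated correlation), a call that ended without ES-EB replicate 3 (0.0739) or iPS-EB replicate 2 (0.269), among other settings. Epithelial genes were higher in 4 of 13 (0.0425, adjusted p = 0.629 with an estimated correlation), a call that ended without ES-EB replicate 2 (0.0755), ES-EB replicate 3 (0.0888) or iPS-EB replicate 2 (0.0665), among other settings. Sarcomere genes were not called (0.877), with a positive median and a negative mean and test.

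Between the embryoid bodies 349 genes were higher and 469 lower in the iPS line. Testing only genes detected on all 21 arrays gave 135 and 185.

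Selected cardiomyocytes of both lines resembled each other in contractile genes. Actc1 measured 13.82 ± 0.07 (SD, n = 3) in ES-CM and 13.91 ± 0.11 in iPS-CM, and Myh6 13.35 ± 0.11 and 12.90 ± 0.37. Of 24 sarcomere genes 0 were called by limma, while 4 had an unadjusted p under 0.05, and the list's adjusted p was 0.948 (0.964 by fry). Of the 24 lists 2 were called. Cell cycle genes were higher in iPS-CM in 19 of 32 cases and lower in 0 (1.08e-18, adjusted p = 0.371 with an estimated correlation). Glycolysis was called at 0.0331 with 1 of 18 members higher (adjusted p = 0.69 with an estimated correlation), and the call ended without iPS-CM replicate 2 (0.141), under 75th percentile scaling (0.0668) and with the mean of all probes (0.131). The helicase subunit Mcm6 was higher by 2.12 ± 0.18 and the mitotic kinase Aurka by 1.77 ± 0.21. The cell cycle list averaged 6.83 ± 0.37 (SD, n = 3) in iPS-CM, 5.70 ± 0.03 in ES-CM and 8.93 ± 0.08 in iPS-EB. Fibroblast genes averaged 5.10 in iPS-CM and 5.13 in ES-CM, and pluripotency genes 4.77 and 4.74. Skeletal muscle genes averaged 6.63 in iPS-CM and 6.91 in ES-CM, and smooth muscle genes 6.883 and 6.895. The phosphatase Dusp2 (5.19 ± 0.20), the cytokine Il15 (3.99 ± 0.20), the small heat shock protein Hspb7 (3.55 ± 0.17), the transporter Slc12a8 (at least 8.29-fold), the kinase subunit Prkag2 (at least 7.44-fold) and phospholamban, Pln (1.43 ± 0.18), were higher in iPS-CM. Lower were the natriuretic peptides Nppa (-1.59 ± 0.19) and Nppb (-1.69 ± 0.30), Isl1 (-2.45 ± 0.32), the calcium sensor Vsnl1 (-3.40 ± 0.19), Dkk3 (-2.93 ± 0.40), Palmd (-2.80 ± 0.17) and S100a1 (-2.78 ± 0.22). Of the stress and heat shock list 7 of 23 members were lower, among them Trib3 (-3.15 ± 0.47) and Chac1 (-2.40 ± 0.61), and the list missed the threshold (0.0503, adjusted p = 0.69 with an estimated correlation). It passed without ES-CM replicate 2 (0.0296), ES-CM replicate 3 (0.0296) or iPS-CM replicate 1 (0.0476) and with the replicate block (0.0364), among other settings. Of the p53 response list 2 of 18 were lower, with Ddit3 at -2.01 ± 0.40, and 1 higher, and it was not called (0.669). The folate enzyme Mthfd2 (-2.59 ± 0.26) was lower. The glutathione transferases Gstk1 (-2.69 ± 0.23) and Gstm5 (-2.64 ± 0.19) were lower. The skeletal muscle list was not called (0.528), with 3 of 8 members lower and 1 higher. Tnni2 (-2.25 ± 0.20) and Ckm (-1.62 ± 0.30) were lower and Chrng higher (1.69 ± 0.16), and the calls ended for Ckm with an offset of 50 and for Chrng with the mean of all probes.

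Between the cardiomyocytes 320 genes were higher and 272 lower in the iPS line. An offset of 50 gave 125 and 128.

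Some line differences were called at every stage. Of 1556 genes called between the lines at any stage, 42 were higher and 12 lower in the iPS line at all 3, where independent lists would share 0.281 and 0.267. Cops8 was higher by 4.17 ± 0.17 undifferentiated and 4.31 ± 0.17 in cardiomyocytes, Tomm22 by 3.22 ± 0.15, 3.29 ± 0.15 and 3.23 ± 0.15, the proteasome subunit Psmd8 by 2.74 ± 0.16, 3.55 ± 0.16 and 3.17 ± 0.16, and the histone chaperone Supt16 by 2.42 ± 0.14, 2.31 ± 0.14 and 2.39 ± 0.14. Twistnb, a subunit of RNA polymerase I, was higher by 2.40 ± 0.23, 3.24 ± 0.23 and 2.41 ± 0.23. Lower at all 3 stages were Xlr4a, Retsat, an enzyme of retinol metabolism (-1.29 ± 0.16, -2.25 ± 0.16 and -1.23 ± 0.16), the DNA repair gene Rdm1 (-1.44 ± 0.22, -1.32 ± 0.22 and -1.31 ± 0.22) and Erdr1 (-1.62 ± 0.25, -1.39 ± 0.25 and -2.19 ± 0.25). Cops8, Psmd8, Xlr4a and Rdm1 had no other detected probe, so their differences rest on a single probe each and could not be checked. At the other detected probes of the 20 shared genes that had any, the median difference was 0.718, against 1.62 at the probe used. Averaged over stages, the other probe differed by 0.258 for Tomm22 (3.25 at the probe used) and 0.304 for Supt16 (2.37). It differed by 2.09 for Twistnb (2.68), 1.54 for Erdr1 (1.73) and 1.3 for Retsat (1.59). In the opposite case, 35 genes were called in opposite directions at 2 stages.

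**Figure D3:**
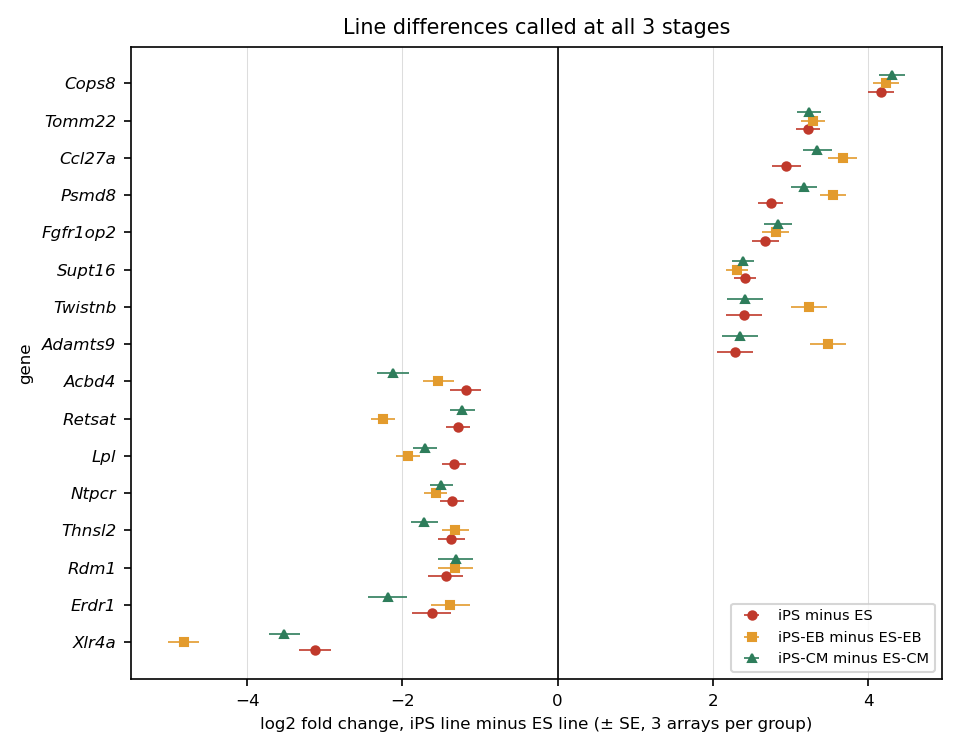
Log2 difference of the iPS line from the ES line (horizontal axis, ± SE, 3 arrays per group) for 16 genes called at all 3 stages, those with the largest changes per direction. Points of a gene lie on the same side of 0, from Cops8 near 4 to Xlr4a under -3.

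Whether differentiation itself differed between the lines was tested by interaction. For the step into embryoid bodies 209 genes changed more upward and 349 more downward in the iPS line, and without ES-EB replicate 1 the higher count was 317. Fibroblast and matrix genes changed more downward in 13 of 33 cases, and 15 adjusted over the list alone (7.29e-11, adjusted p = 0.705 with an estimated correlation). Dcn differed by -3.18 ± 0.45 and Bgn by -2.94 ± 0.40, in a list that averaged higher on iPS replicate 1 (7.66) than on any other undifferentiated array. Glycolytic genes changed more upward as a list (0.000867, adjusted p = 0.705 with an estimated correlation), though 0 of 18 were called by limma, 1 adjusted over the list alone and 10 at an unadjusted p under 0.05. For the step into cardiomyocytes 477 genes changed more upward and 378 more downward in the iPS line. Cell cycle genes did so upward in 21 of 32 cases and downward in 1, Plk1 (9.89e-15, adjusted p = 0.168 with an estimated correlation). The probe of Plk1 measured 4.44 in ES-EB, where 2 of 3 arrays detected it, and 8.34 in iPS-EB. Its signal thus had little room to fall in the ES line, although the cell cycle list averaged 8.89 in ES-EB. No other probe of Plk1 was detected, so whether this probe misses the transcript in the ES line was not tested. Primitive streak genes changed more downward in 7 of 10 (1.93e-07, adjusted p = 0.168 with an estimated correlation). That list averaged 5.45 ± 0.24 (SD, n = 3) in ES-EB and 7.41 ± 0.56 in iPS-EB, and 4.77 ± 0.04 in ES-CM and 4.74 ± 0.15 in iPS-CM, so this largely restates the difference between the embryoid bodies.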

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

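The first results in this part stood out because the change within the ES line and the change within the iPS line differ by an interaction test. The patterns weighed after them are direct differences between the lines, not interactions. Chosen after the result was seen were the tests of feeder cells in iPS replicate 1, the splits of whole cultures and the tests of whether 1 array decides a difference. No group is large enough for a test of single arrays standing apart.

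At the step into embryoid bodies 209 genes changed more upward and 349 more downward in the iPS line, and without ES-EB replicate 1 the upward count was 317. Of 100 regroupings of the line labels within stages, 8 gave as many calls, the real one (558) included, and the highest other gave 1074. At the step into cardiomyocytes the counts were 477 and 378. There 5 of 100 regroupings gave as many, with 855 in the real one and 2221 in the highest other. Chance is not excluded by these counts, but they are a poor measure of it. They permute each stage apart, although the stages share cultures of the same passage. The high counts point to a structure of the samples: other counts as large arose only where 0 arrays kept their line at one stage and 4 or 6 of 6 at the other, or 2 and 6. This exchanges the lines at 1 stage, wholly or in part, and turns line differences into an interaction. With each culture kept whole over the stages there are 10 splits, too few for a share under 0.05. In each step 1 of them, the real one, gave as many calls, with 558 and 855 in the real one and 0 in the highest other.

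Values that follow are differences of log2 changes, iPS line minus ES line, and where a group did not detect a gene they rest on its background level. At the step into embryoid bodies the lowest were those of Lyz1 (-6.60), Ctsj (-5.21), Cryba1 (-4.99), Zscan4c (-4.62) and Gpnmb (-4.41). The highest were those of Cpm (3.06), Pisd-ps2 (2.65), Samd3 (2.58), Shh (2.50) and Foxd4 (2.40). The macrophage gene Lyz2 (-3.77) and the stress gene Gadd45a (-3.14) changed more downward, as did the matrix genes Dcn (-3.18), Bgn (-2.94) and Lum (-2.82) and the pluripotency genes Fbxo15 (-2.24) and Zfp42 (-2.23). The mesoderm factor Mesp1 (2.10) and the endoderm factor Foxa1 (1.33) changed more upward. List medians differed for pluripotency (-0.683), glycolysis (0.45) and the fibroblast and extracellular matrix list (-0.879). The pluripotency call (adjusted p = 0.0111) ended without ES replicate 2 (0.0591), without iPS-EB replicate 3 (0.281) and with genes detected on all arrays only (0.354), in a range from 5.88e-06 to 0.761. With an estimated correlation its adjusted p = 0.761, and 0 of the 3 called lists of this step hold.

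At the step into cardiomyocytes the lowest were Olig1 (-4.78), Fgf5 (-3.71), Lhx1 (-3.38), Rab38 (-3.25) and Fgf8 (-3.20), and the highest Cryba1 (5.40), Dusp2 (5.27), Ctsj (4.39), Il15 (4.12) and Rhox9 (3.85). Genes of the primitive streak and epiblast, Eomes (-2.96), Gsc (-2.96) and Otx2 (-2.69), changed more downward. So did the receptor Flt1 (-2.85), the junction gene Cldn6 (-2.73), the cardiac genes Isl1 (-3.05) and Nppa (-1.86) and the chaperone Hspa1a (-1.70). More upward changed Zfp42 (3.59), Fbxo15 (3.15), Robo4 (2.85) and the cell cycle genes Tyms (2.12), Cdca3 (2.08) and Mcm6 (2.02). Between the embryoid bodies themselves, Zfp42 differed by -3.72, Fbxo15 by -3.24, Cryba1 by -5.39 and Ctsj by -5.19. Olig1 differed there by 4.6, Fgf5 by 3.21 and Lhx1 by 3.52. The interactions of these genes largely restate the difference between the embryoid bodies. With the mean of all probes of a gene the calls for Hspa1a, Robo4, Tyms and Mcm6 ended. List medians differed for pluripotency (0.714), fatty acid oxidation and oxidative phosphorylation (0.433), cell cycle (1.26), endothelium (0.576), epithelium (-0.541) and primitive streak and early mesoderm (-1.92). Pluripotency genes averaged 4.74 in ES-CM and 4.77 in iPS-CM, endothelial genes 4.50 and 4.47, and epithelial genes 4.52 and 4.46. As for the primitive streak list, these medians largely restate the difference between the embryoid bodies.

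With an estimated correlation all 6 of these list calls ended: pluripotency and epithelium at an adjusted p of 0.837 each, the other 4 at 0.168. For pluripotency (adjusted p = 0.0244, range 0.000155 to 0.837) the call also ended when leaving out ES-EB replicate 2 (0.0975), ES-EB replicate 3 (0.0792) or iPS-EB replicate 3 (0.26). Epithelium (0.0244, range 1.32e-05 to 0.837) ended without ES-EB replicate 2 (0.0975), ES-EB replicate 3 (0.122) or iPS-EB replicate 2 (0.0814). Fatty acid oxidation (0.00207, range 4.98e-05 to 0.168) and endothelium (0.0132, range 0.000357 to 0.168) ended under 75th percentile scaling (0.0699 each).

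The first pattern weighed is the 54 genes called between the lines at all 3 stages, such as Cops8 and Xlr4a. None of 99 other regroupings gave any such gene, so 1 of 100 gave as many (54, highest other 0). This count cannot decide on a chance arrangement. At a single stage, the highest count of any other split was 1 between undifferentiated cells and 0 between cardiomyocytes. Other regroupings could thus hardly give a shared gene, and they permute each stage apart although the stages share cultures. With cultures kept whole, 10 splits are too few for a share under 0.05 (1 gave as many, with 54 in the real one and 0 in the highest other). A sequence variant under a probe could set 1 line apart at that probe alone. At the other detected probes of 20 shared genes the median difference was 0.718 (interquartile range 0.233 to 1.3), against 1.62 at the probe used, with 7 genes at 1 or more and 7 under 0.5, Tomm22 (0.258) and Supt16 (0.304) among the latter. In 3 genes, Fgfr1op2, Rmdn3 and Wdr82, named after their values were seen, the other probes differed in the opposite direction. For 1090 genes called from embryoid bodies to cardiomyocytes in both lines, the median at the other probes was 1.15 against 1.79. Of these, 57.4% changed by 1 or more at the other probes. The genes under 0.5 were all higher in the iPS line, a split by direction seen afterwards. Among lower genes the other probe differed by 1.29 (Acbd4), 1.54 (Erdr1), 1.3 (Retsat), 1.34 (Thnsl2) and 0.542 (Sfi1). For Acbd4, Erdr1, Retsat and Thnsl2 these values argue against a variant under 1 probe alone. Variants and true line differences cannot be told apart for the shared genes as a set, and a biological difference of the lines stays open, untested.

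The second pattern is the higher fibroblast and matrix genes in iPS than in ES cells. A candidate source is fibroblast-like cells, such as the feeders, in iPS replicate 1. The test took the 200 genes brightest in fibroblasts over ES cells, list and blood genes left out. Of these, 89% were brighter in iPS replicate 1 than in the mean of the other iPS arrays, against 45.6% of all genes. The most abundant list genes went the same way, with Lox at 9.22 in iPS replicate 1, 6.99 and 7.01 in the others, 7.06 in ES cells and 13.82 in fibroblasts, though 20 of 33 members were detected in all ES arrays and 1 belongs to another list. This array does not make up the whole difference, since without it the list median was 0.381 higher in iPS cells (adjusted p = 0.0013, range over alternatives 1.34e-08 to 0.805), with 5 members called. Feeders and other fibroblast-like cells were not separated, and a biological difference between the lines stays open, untested.

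The last pattern is the higher cell cycle genes in iPS-CM than in ES-CM. Unselected cells of the average iPS-EB make-up, which puromycin would remove, are argued against: the cell cycle excess needs a median share of 11.7% iPS-EB RNA (28 genes, interquartile range 8.61 to 17.6). The pluripotency, epithelium, fibroblast and endothelium lists allow a median of -0.0986% (48 genes, interquartile range -0.277 to 0.337). This pooled median rests mostly on pluripotency, with 26 genes, against 10 of fibroblasts, 8 of epithelium and 4 of endothelium. The fibroblast genes alone had an upper quartile of 1.65%. No single array decides it, as at least 16 members were called whichever array was left out, with adjusted p at most 3.13e-16. More dividing cardiomyocytes, or another dividing cell type, may explain the higher cell cycle genes and stay open as untested hypotheses.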

How the results depend on the processing

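Chosen after seeing the data was leaving out iPS replicate 1 and ES replicate 2 together. Counts are given as higher and lower genes, and unless a reason is given the cause was not tested.

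Of 1035 named gene results, 991 passed the threshold, and 0 reversed under any alternative. Calls ended for 170 with the mean of all probes, 115 with an offset of 50, 81 without background correction, 35 under 75th percentile scaling, 26 with matrix values, 24 with only the groups compared, 19 with array weights, 14 with no filter and 2 with the replicate block. Leaving out 1 array ended 219 over all arrays and results, and the combination added later 24. Of the list results, an estimated correlation ended 103 calls, leaving out 1 array 37 over all arrays, genes detected on all arrays 35, 75th percentile scaling and the mean of all probes 13 each, and only the groups compared 10. An offset of 50 ended 9, fry 7, the combination added later 7, array weights and no filter 4 each, no background correction 3, and matrix values 1. The replicate block ended 3, all in iPS-EB against iPS: endothelium, fibroblast and extracellular matrix, and reprogramming factors (0.056 each). It added the call of stress and heat shock between cardiomyocytes (0.0364). Calls were also gained: 50 with fry, 35 over all arrays left out, 17 with no filter, 10 with only the groups compared, 7 under 75th percentile scaling, 5 each with genes detected on all arrays and without background correction, 3 with the combination added later, and 2 each with array weights, the mean of all probes and matrix values.

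Without background correction the counts were 158 and 111 for iPS against ES cells (299 and 249 as reported), 426 and 221 for ES-EB against ES, and 491 and 317 for iPS-EB against iPS. Between the lines they were 187 and 263 in embryoid bodies and 159 and 154 in cardiomyocytes. The interactions gave 91 and 213 (embryoid bodies) and 274 and 207 (cardiomyocytes), and 22 genes were higher at all 3 stages.

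An offset of 50, which shrinks changes of dim genes by construction, gave 119 and 89 for iPS against ES cells, 356 and 181 for ES-EB against ES, 421 and 285 for iPS-EB against iPS, and 1152 and 1306 for ES-CM against ES-EB. The lower count of iPS-CM against iPS-EB was 1188. Between the lines it gave 165 and 230 in embryoid bodies and 125 and 128 in cardiomyocytes. The interactions gave 75 and 181, and 236 and 181. At all 3 stages 16 genes were higher and 7 lower.

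Testing only genes detected on all arrays lowers counts, since fewer genes are tested. It gave 114 and 83 for iPS against ES cells, 1356 and 1047 for iPS cells against fibroblasts, 295 and 151 for ES-EB against ES, and 355 and 212 for iPS-EB against iPS. ES-CM against ES-EB gave 949 and 969, iPS-CM against iPS-EB 827 and 933, ES-CM against ES 1218 and 1201, and iPS-CM against iPS 1219 and 1237. Between the lines it gave 135 and 185 in embryoid bodies and 155 and 134 in cardiomyocytes, with 75 and 116, and 145 and 146, for the interactions. At all 3 stages 16 genes were higher.

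The mean of all probes gave 182 and 160 for iPS against ES cells, 221 and 300 between embryoid bodies, 202 and 162 between cardiomyocytes, and 105 and 211, and 295 and 211, for the interactions. The higher counts of ES-EB against ES and iPS-EB against iPS were 407 and 444, and the lower count of iPS-CM against iPS-EB was 1196. Scaling to the 75th percentile gave 190 higher genes for iPS against ES cells and 243 lower for the cardiomyocyte interaction. Array weights gave 334 higher genes for the embryoid body interaction.

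With 1 array left out, the higher count of the embryoid body interaction ranged from 151 (without ES-EB replicate 2) to 317 (without ES-EB replicate 1). Other counts stayed within 1.5 times: iPS against ES cells ranged from 251 to 338 higher and 230 to 284 lower, and cardiomyocytes between the lines from 272 to 371 and 255 to 322. The correlation of both lines' changes ranged from 0.656 to 0.725, from 0.869 to 0.890 and from 0.910 to 0.922 for the 3 steps.

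The direction of the test turned for a pair of lists, while neither median changed sign. The sarcomere list in iPS-CM against iPS-EB had a median of 0.05108 with genes detected on all arrays (4.39 as reported; adjusted p = 0.946, range 5.98e-18 to 0.946), where fewer members are left. The glutathione list in ES-CM against ES-EB had a median of 0.04249, as reported, and a downward fry call (0.0428, range 0.0428 to 0.982). Scaling to the 75th percentile moved the median of all genes by over 0.1, to -0.134 for iPS against ES cells, 0.284 for iPS cells against fibroblasts, -0.104 for ES-EB against ES, -0.196 for ES-CM against ES-EB, -0.385 for ES-CM against ES, -0.259 for iPS-CM against iPS, -0.0991 for iPS-EB against iPS, -0.1 between embryoid bodies and 0.0983 for the cardiomyocyte interaction. Genes detected on all arrays gave 0.151 for iPS cells against fibroblasts.

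Slide as a block was not run, as no slide is given, and the replicate block was not run for iPS cells against fibroblasts. Signal over background limits dim genes: 29.2% to 39.5% of probes per array were detected.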

Other observations

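None of the tests in this part was chosen after the result was seen. For comparisons of 3 arrays against 3, 10 splits are too few for a share under 0.05. In each, 1 split, the real one, gave as many calls. The real count and the highest other were 548 and 1 for iPS against ES cells, 1204 and 14 for ES-EB against ES, 1376 and 4 for iPS-EB against iPS, and 3736 and 0 for ES-CM against ES-EB. They were 3339 and 2 for iPS-CM against iPS-EB, 4509 and 2 for ES-CM against ES, 4471 and 0 for iPS-CM against iPS, 818 and 96 between embryoid bodies and 592 and 0 between cardiomyocytes. Of the 10 splits, 4 part all 3 pairs of equal replicate number, the real one included, and among these the highest other was 13, between embryoid bodies, and 0 in the other comparisons.

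Some genes were bright in 1 group alone. The placental protease Ctsj measured 9.52 ± 0.92 (SD, n = 3) in ES-EB and 5.06 ± 0.80 or less in the other groups. The phosphatase Dusp2 measured 10.19 ± 0.11 in iPS-CM and 5.54 ± 0.50 or less elsewhere.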
